A study of Mus musculus with 2 samples.

How the data were processed

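The series held 2 libraries from mouse embryonic brain at embryonic day 13, an H2AZ ChIP of neural progenitor cells and an input, with 1 library per group. One peak list was used. Each line gives a chromosome, a start, an end, a peak name and a score, without a header. The score is the authors' own value per peak, deposited in descending order, and what it measures is not named in the file; it was used only to rank, filter and describe peaks within this list. The other deposited columns used were the start and end, which the authors gave counted from 0; starts are printed here counted from 1.

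The peak names carry the name of the caller MACS, per the deposited file; its version and settings are not given in the sources used here, nor is whether the input library was its control. CASAVA 1.4, FastQC, Bowtie2 2 and the build mm9 are named in the submitters' processing notes. The peak numbers run to 32646 and 21592 peaks are listed (66.1%), so the list is a part of a longer one, and the criterion is not given in the sources used here. A gene without a listed peak may therefore have had a peak in the longer list. Read numbers were not analysed here, so depth is unknown, no enrichment over input was computed, and no interval covers more than counting error.

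The build was checked from the positions. With the gene table of GRCm38.p6 from RefSeq, 51.6% of peaks lay within 1 kb of a protein-coding gene boundary. This share was 12.0 to 12.2% with the peaks shifted by 10 or 20 kb either way, 11.0 to 11.4% by 100 kb and 8.26 to 8.32% by 1000000 bp, and every autosome and X showed the same fall after a shift of 1000000 bp. Positions were therefore read as GRCm38, not mm9 as in the processing notes, and none was converted.

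The 46 peaks whose numbers follow the last peak of the Y chromosome stand out of order on the chromosomes they are listed on; they were left out of all comparisons with genes and chromosomes, leaving 21546. In the gene table, 348 genes on other sequences labelled with a chromosome were left out, leaving 49595 annotated genes, of which 21774 are protein-coding. The table gives the outermost start and end of each gene and was used without strand, transcripts or genome sequence. The planned analyses around transcription start sites were therefore made around gene boundaries, meaning either end of a gene, and gene interiors were not split into exons and introns. Promoter CpG content, the lists restricted to CpG-rich promoters, the position of peaks along the direction of transcription and the 5' end alone were planned and not run. An internal promoter of a gene counts as interior. The score given for a gene is that of its highest boundary peak, which can lie outside the gene.

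A peak was at a boundary if it overlapped the 1 kb on either side of it by at least 1 bp. Random placement kept each peak's width and chromosome and used the span between the first and last annotated gene of the chromosome, 1000 times; assembly gaps within that span were not removed. Chromosome densities used the same span, and for the X to autosome ratio the number of peaks on X was drawn 1000 times from a binomial distribution by span length, without keeping peaks on their chromosomes. Gene lists were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 18 lists and a threshold of 0.05; all list symbols were found in the gene table. Genes are not independent replicates, so each p describes this one list of peaks. Added after seeing the data were 10000 random lists matched on gene length and neighbouring boundaries, a background of genes with no other boundary within 2 kb, any peak in the gene or its flanks, and peaks shifted by 10 kb. The other checks, chosen in advance, were the higher-scoring peaks (a score at or above the median), merged peaks, windows of 500 bp, 2 kb and 5 kb, other overlap criteria, all annotated genes, density per gene and other distance limits.

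The lists and the rule for named genes were fixed before the data were examined. The rule takes Setd2, H2az1, H2az2 and Nkx2-4; the 20 protein-coding genes with the highest-scoring boundary peak, leaving out olfactory receptor and predicted genes; of each list the 4 members with the highest-scoring peak and the first 3 in alphabetical order without; the 5 widest and the 5 highest-scoring peaks; and the 3 windows of 100 kb with the most peaks. Some genes that the rule takes are not reported here.

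The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated data. Of 200 genes given a peak at 1 end among randomly placed peaks, 200 were found, and over 21774 genes the calls differed in 0 from a direct comparison of every gene with every peak. Of 200 random lists of 20 genes, 3 had an unadjusted p under 0.05 and 0 were called. Of 40 randomly placed peak lists, 2 had a boundary p under 0.05, and a list built to have 52.9% of peaks at boundaries gave 53.0%.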

Results

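Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map the histone variant H2AZ in neural progenitor cells of the brain of C57BL/6 mouse embryos at embryonic day 13. H2AZ replaces the canonical histone H2A in a part of the nucleosomes and is deposited and removed by dedicated chromatin remodelling complexes. The series held 1 H2AZ ChIP library and 1 input library, and the deposited values were a single list of peaks, 21546 of which were used here, each with a position and a score given by the authors' peak caller. With 1 library per group there was no replicate check of any value, and no test compared ChIP with input. The number of reads per library was unknown, so all comparisons were made within this list, between regions or groups of genes. Intervals are 95% exact (Clopper-Pearson or Poisson) intervals unless named otherwise, and cover counting error only.

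The deposited peaks, including 46 that stood out of order and were not used further, covered 42.9 Mb. Their median width was 1922 bp (quartiles 1542 and 2321 bp, range 534 to 7492 bp) and their median score was 11.9 (quartiles 7.95 and 17.9). Wider peaks had higher scores, with a Spearman correlation across peaks of 0.55; peaks are not independent replicates. No peaks overlapped, and the median gap between neighbours was 39.1 kb. Coordinates are those of the deposited list, whose positions matched the gene boundaries of GRCm38.

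The first question was where H2AZ lay relative to genes. Of the 21546 peaks placed on chromosomes, 11127 (51.6%, interval 51.0 to 52.3%) lay within 1 kb of a boundary of a protein-coding gene, against a mean of 6.01% in 1000 random placements of the same widths on the same chromosomes, which is 8.59 times as many. By the peak midpoint, 47.4% of peaks lay at a gene boundary (3.20% at random), 22.6% in a gene interior (39.3% at random) and 30.0% between genes (57.5% at random). The share of peaks at a boundary rose with the score. In the 10% of peaks with the lowest scores 10.5% (9.23 to 11.9%) lay at a boundary, and in the 10% with the highest scores 89.0% (87.6 to 90.3%) did. The one-sided permutation p for the boundary share was 0.001 and the two-sided permutation p for each location class was 0.002, the smallest that 1000 placements can give. Against the same peaks shifted by 10 kb, a background chosen after seeing the data that keeps peaks in gene-rich regions, the excess was 4.26 times.

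**Figure D1:**
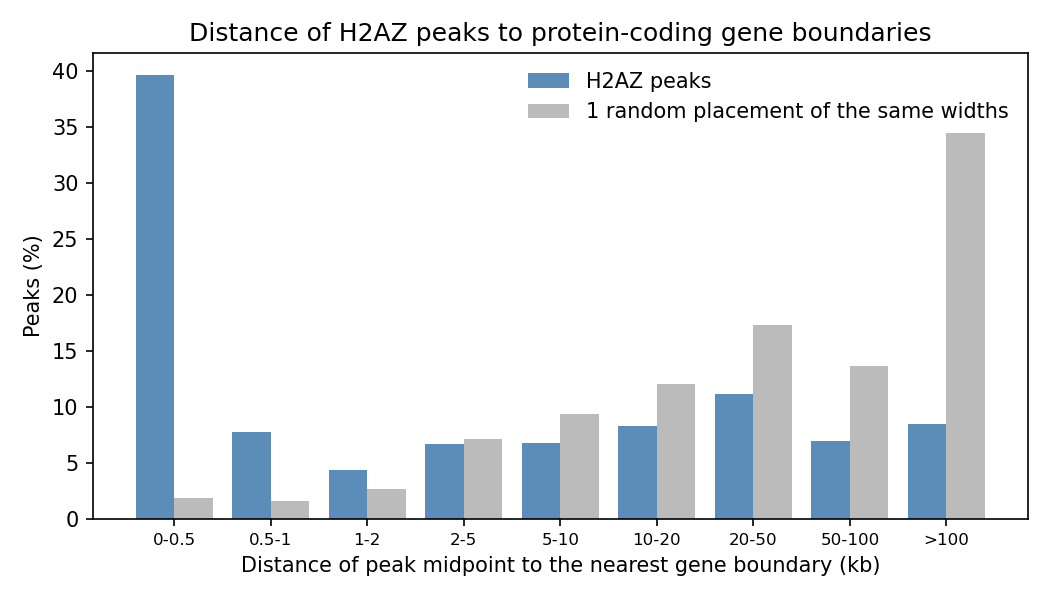
Percent of H2AZ peaks (blue) and of 1 random placement of the same widths (grey) by the distance of the peak midpoint to the nearest boundary of a protein-coding gene, in kb. Within 0.5 kb lay 39.7% of the peaks and 1.81% of the randomly placed ones.

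**Figure D2:**
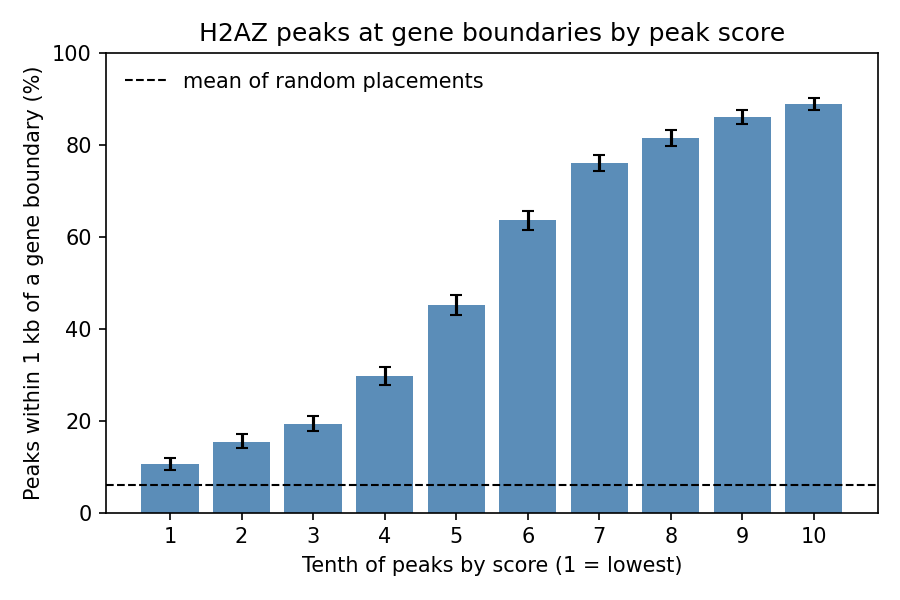
Percent of H2AZ peaks within 1 kb of a protein-coding gene boundary, in 10 groups of peaks ordered from the lowest (1) to the highest (10) score, with 95% exact intervals as error bars and the mean of random placements as a dashed line. The share was 10.5% in the lowest group and 89.0% in the highest.

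Of 21774 protein-coding genes, 12060 (55.4%) had a peak within 1 kb of a boundary. The strand of the genes was not used here, so the 5' and 3' ends could not be named, but peaks marked 1 end of a gene rather than both. Among 7300 genes of at least 10 kb with no other boundary within 5 kb, 4190 had a peak at 1 end, 94 at both ends and 3016 at neither. Were the ends independent, 656 genes would have had both. The midpoint of the same genes had a peak in 128 cases (1.75%). Of the 9714 genes with no boundary peak, 1249 (12.9%) held a peak in their interior, so a gene described as lacking a boundary peak need not lack H2AZ peaks. Among genes named below as lacking one, Sox1 (6.26), Neurod1 (6.9), Emcn (7.16), Foxa1 (7.16) and Ywhaz (10.4) held an interior peak of the score in brackets. Other such genes are given where they are named.

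The genes at the centre of the study all had a boundary peak. Setd2, which encodes the methyltransferase that makes histone H3 trimethylated at lysine 36, had a peak of score 22.1 on chromosome 9 from 110530881 to 110533668, with its midpoint 226 bp from the boundary and a rank of 2455 by score. H2az1, which encodes H2AZ itself, had a peak of score 14.7 on chromosome 3 from 137867188 to 137868810, beside a boundary of Dnajb14, and the peak overlapping H2az1 scored 12.83. H2az2, the paralogue, had a peak of score 10.7 on chromosome 11 from 6443496 to 6445518. Nkx2-4, a homeobox gene, had a peak of score 12.7 on chromosome 2 from 147083643 to 147085823. With 4 of 4 genes the study list was too small to be called against the 55.4% of other genes (Fisher's exact test, two-sided, adjusted p = 0.201).

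The highest-scoring boundary peaks lay at genes of protein turnover and membrane traffic. The peak at Uhmk1, a kinase gene, had the highest score of the list (chromosome 1, 170214397 to 170216533), followed by the peak shared by Atmin and Cmc2 (38.5; chromosome 8, 116942507 to 116944498). Stx17, a syntaxin gene, had a score of 37.6, the deubiquitinase gene Usp25 37.3, and the mitochondrial kinase gene Pink1 and Rnf169 each 36.7. Further genes of the top 20 ran from C1galt1 (35.9) through Shq1 (35.9), Hip1r and Vps8 (35.8 each), and Actrt3, Cmss1, Pomgnt2 and Rnf180 (34.9 each) to Fam98c, Rasgrp4 and Zfp493 (34.6 each) and Rundc3b (34.3). Fam98c and Rasgrp4 shared 1 peak, which lay outside Rasgrp4, and the Actrt3 peak lay outside Actrt3. The peak with the third-highest score of the list, 37.9, lay in the interior of Sgo2a, 10804 bp from its nearer boundary (chromosome 1, 57995038 to 57997251). These genes were ranked, and no test was made of the functions they share.

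The second question was which gene groups carried H2AZ, and 18 gene lists were tested. Neural progenitor genes mostly had a boundary peak, but peaks of low score, a trait shared with other lists. In the radial glia and neural progenitor list 14 of 18 genes had one (77.8%, interval 52.4 to 93.6%), among them Hes1, a Notch effector (score 21.8), Vim (12.95), Hes5 (11.9) and Id4 (11.04), and Prom1 and Sox1 did not. The Hes1 and Hes5 peaks lay outside the genes, the latter beside a boundary of Pank4, and the peaks overlapping Hes1 and Hes5 scored 5.24 and 10.46. In the list of intermediate progenitors and neurogenesis 12 of 14 genes had one (85.7%), among them the Notch ligand genes Dll3 (21.6) and Dll1 (15.5), Insm1 (14.9) and Hes6 (14.6), and Neurod1 and Rcor2 did not. The median score of these boundary peaks was 8.35 for the radial glia list and 10.7 for the intermediate progenitor list, against 17.1 over all protein-coding genes with a boundary peak. These medians lay at percentiles 0 and 0.08 of 10000 random lists of the same size, a description of this library only. Low medians were also found for developmental regulators of other lineages (8.35, percentile 0.01), astrocytes and oligodendrocytes (8.05, 0.17), Hox genes (9.55, 0.36), histones (8.05, 0) and housekeeping genes (12.38, 0.84), so they did not set the progenitor lists apart. Neither list was called by Fisher's exact test (two-sided, Benjamini-Hochberg over the 18 lists), with adjusted p = 0.0994 for radial glia and 0.0518 for intermediate progenitors. With windows of 2 kb both were called (Fisher adjusted p = 0.0497 and 0.0119), and with windows of 5 kb the intermediate progenitors were (0.0286). Against random lists matched on gene length and on neighbouring boundaries, a check chosen after seeing the data, both were called (permutation adjusted p = 0.0057 and 0.0009). The matched lists had mean shares of 41.8 and 36.2%, below the 55.4% of other genes. They were not matched on gene family, and olfactory receptor genes, of which 1 of 1105 had a boundary peak, may lower these means. The calls may thus reflect the comparison genes as well as the progenitor genes, which was not tested. With the higher-scoring peaks alone (those with a score at or above the median) the radial glia share turned to 16.7% against 44.4% of other genes (Fisher adjusted p = 0.0358) and the intermediate progenitor share to 35.7% (Fisher adjusted p = 0.673).

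Neuronal genes had a boundary peak in 12 of 18 cases (66.7%, Fisher adjusted p = 0.538), led by the synaptic gene Syt1 (score 25.1), Elavl4 (22.1), the neurofilament gene Nefm (20.3) and Ncam1 (17.1), whereas Dcx, Map2 and Mapt had none. Genes of astrocytes and oligodendrocytes had one in 5 of 14 cases (35.7%, Fisher adjusted p = 0.219), with the myelin genes Mbp (20.9) and Cnp (20.02) above Olig1 (8.05) and Aldh1l1 (6.77). Aqp4, Gfap and Mag had no boundary peak, though each held an interior peak (highest scores 6.18, 16.1 and 10.1). Endothelial genes had one in 4 of 12 cases (33.3%, Fisher adjusted p = 0.209), namely Kdr (16.4), Flt1 (11.9), Sox17 (7.61) and Sox18 (6.38), and Cdh5, Cldn5 and Emcn had none. Erythroid genes had one in 6 of 12 cases (50.0%, Fisher adjusted p = 0.822), with Ank1 at 23.0, Ermap at 14.6 and Klf1 at 11.8, and Alas2, Gata1 and Hba-a1 without. The Ermap peak lay outside the gene, at a boundary of Zfp691. Alas2 and Gata1, like Dcx, lie on X, where 40.2% of protein-coding genes had a boundary peak, against 56.8% on autosomes. None of these 4 lists was called by Fisher's exact test. With windows of 5 kb the astrocyte and oligodendrocyte share was 71.4%, above the 60.8% of other genes and not called, and with the higher-scoring peaks alone the neuronal share fell to 38.9%, below the 44.4% of other genes and not called.

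Genes of the cell cycle and of H2AZ turnover had a boundary peak more often than other genes. In the cell cycle list 24 of 27 genes had one (88.9%, Fisher adjusted p = 0.00138), including E2f1, a transcription factor of S phase entry (score 29.2), the replicative helicase gene Mcm6 (26.3), Cdc20 (24.8) and Aurka (20.6), and Ccne1, Cdk6 and Cdkn1a had none. All 14 genes of the H2AZ deposition and removal list had one (interval 76.8 to 100%, Fisher adjusted p = 0.00173), with the highest scores at the H2AZ chaperone gene Anp32e (24.8), Mbtd1 (22.1), Znhit1 (20.6) and Kat5 (18.8). The peaks of Mbtd1, Znhit1 and Kat5 were also at boundaries of Utp18, Plod3 and Rnaseh2c, and the peak overlapping Kat5 scored 15.51. Housekeeping genes had one in 14 of 16 cases (87.5%, Fisher adjusted p = 0.0206), led by Gusb (23.9), Sdha (21.5), Tbp (21.2) and B2m (21.1), and not at Tubb5 or Ywhaz. Zinc finger genes of the Zfp series had one in 287 of 367 cases (78.2%, Fisher adjusted p = 4.26e-19), with Zfp493 at 34.6, Zfp69 at 33.4 and the pair Zfp398 and Zfp786 sharing a peak of 33.1. Zfp109, Zfp217 and Zfp229 had no boundary peak, but each held an interior peak (24.5, 26.9 and 16.5). The peaks of Aurka, Sdha and Tbp were also at boundaries of Cstf1, Ccdc127 and Psmb1. The housekeeping call ended against matched random lists (permutation adjusted p = 0.0792), and the cell cycle and housekeeping calls ended with the higher-scoring peaks alone (59.3 and 50.0%, Fisher adjusted p = 0.188 and 0.813). In the H2AZ turnover list 11 of the 14 genes had another gene's boundary within 2 kb, and the remaining genes were too few to be called (Fisher adjusted p = 0.161).

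Chromatin modifiers, the list closest to the lysine 36 methylation of the series title, were not called. A boundary peak was present at 9 of 17 (52.9%, Fisher adjusted p = 1), with Setd2 highest (22.1), then Suz12 of the Polycomb repressive complex (20.2), the demethylase gene Kdm4a (17.7) and Ash1l (16.1). The Ash1l peak was also at a boundary of Dap3. The DNA methyltransferase genes Dnmt1, Dnmt3a and Dnmt3b had no boundary peak, but Dnmt3a held an interior peak of score 26.3 and Dnmt1 one of 14.9.

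Hox genes, genes of other tissues, olfactory receptor genes and histone genes had boundary peaks less often. Only 7 of 39 Hox genes had one (17.9%, interval 7.54 to 33.5%, Fisher adjusted p = 1.36e-05), with Hoxd8 (15.8), Hoxd1 (14.9), Hoxd9 (10.9) and Hoxa4 (9.55) highest, and Hoxa10, Hoxa11 and Hoxa2 without. The Hoxa4 peak lay outside the gene. Microglial and white blood cell genes had one in 2 of 14 cases (14.3%, Fisher adjusted p = 0.00538), namely Spi1 (14.9) and Cd68 (10.7), the latter beside a boundary of Mpdu1, and the complement genes C1qa and C1qb and Aif1 had none. Terminal genes of other tissues had one in 4 of 20 cases (Fisher adjusted p = 0.00538): Apoa1 (15.2), Myh7 (11.3), Tnnt2 (10.2) and Cela1 (7.65), with none at Adipoq, Alb or Cpa1. The Myh7 peak lay outside the gene, and the peak overlapping Myh7 scored 5.37. Of 1105 olfactory receptor genes 1, Olfr658 (11.04), had one, and Olfr1, Olfr10 and Olfr1000 are among those without. The Fisher p was too small to be held as a number. Whether reads could be placed uniquely at these similar genes, or at the histone genes that follow, was not examined. Replication-dependent histone genes had one in 22 of 63 cases (34.9%, Fisher adjusted p = 0.00402), with H1f5 at 13.7 and H2ac20, H2ac21 and H2bc21 sharing a peak of 10.4, and H2ac1, H2ac10 and H2ac11 without. Developmental regulators of other lineages had one in 8 of 20 cases (Fisher adjusted p = 0.219), including Isl1 (16.7), Gata6 (10.7) and Myod1 (8.65) but not Cdx2, Foxa1 or Foxa2, and this list was called lower with the higher-scoring peaks alone (10.0%, Fisher adjusted p = 0.00342). Against matched random lists the histone call ended (permutation adjusted p = 0.871), and the Hox, microglial and terminal calls were kept (0.0009, 0.0036 and 0.0232). Among genes with no other boundary within 2 kb, the calls for the Hox, microglial and terminal lists ended (Fisher adjusted p = 0.0952, 0.0944 and 0.0711), though their shares of 26.9, 11.1 and 18.75% stayed below the 47.6, 47.5 and 47.5% of other genes, and the histone share turned to 50.0% against 47.5% of other genes.

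**Figure D3:**
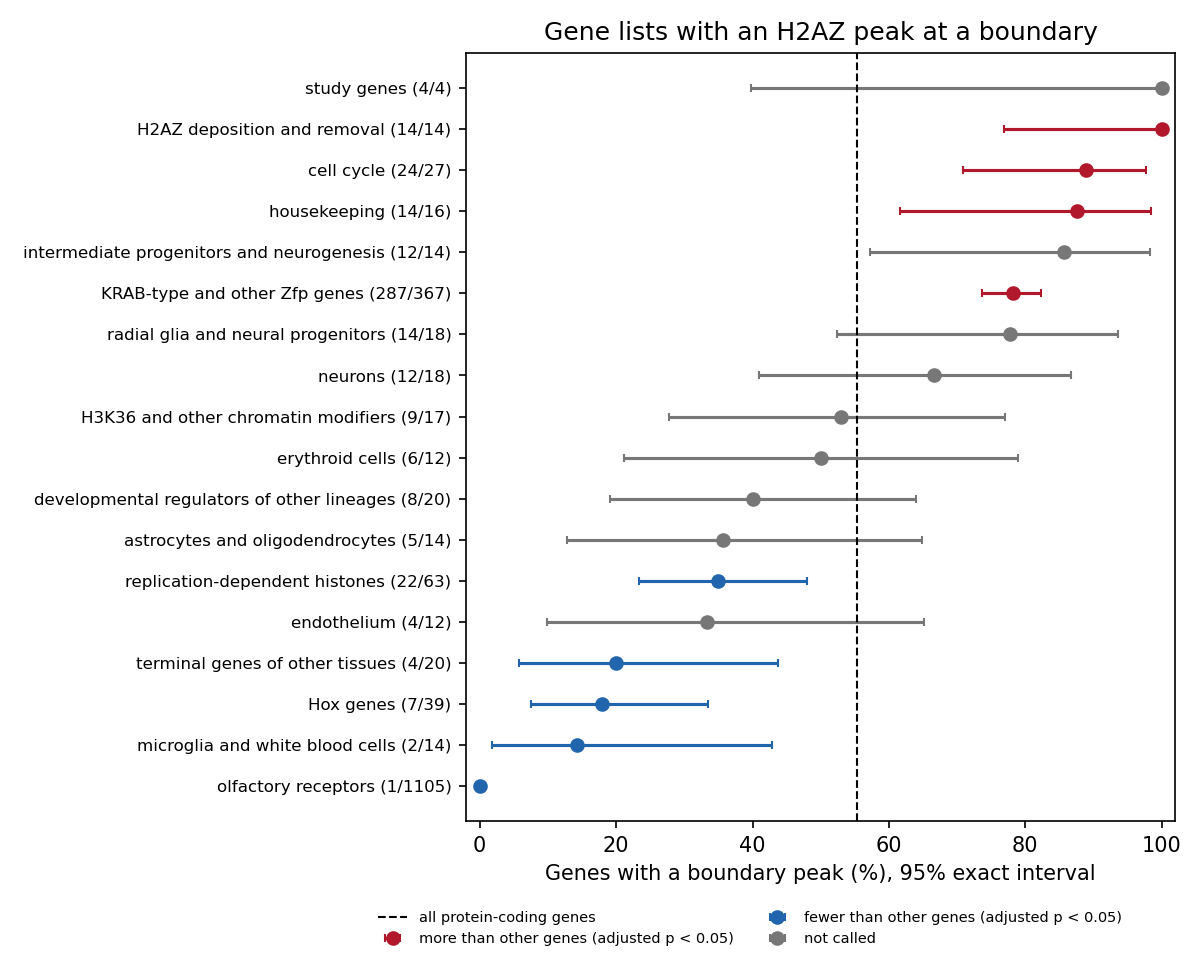
Percent of the genes of each list with an H2AZ peak within 1 kb of a boundary, with 95% exact intervals as bars and the number of genes in brackets; the dashed line is the share of all protein-coding genes (55.4%) and the colours give the call by Fisher's exact test. Called shares ran from 1 of 1105 olfactory receptor genes to 14 of 14 genes of H2AZ deposition and removal.

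Peak density differed between chromosomes. Chromosome 11 had the highest density among autosomes, 13.4 peaks per Mb (interval 12.7 to 14.1), and chromosome 14 the lowest, 6.61 (6.16 to 7.08). Per protein-coding gene the order differed. Chromosome 11 had 0.993 peaks and chromosome 14 had 0.946, against 1.02 over all autosomes, while chromosome 12 had the most (1.35) and chromosome 7 the fewest (0.743). The X chromosome had 494 peaks, or 2.95 per Mb, against 8.76 on autosomes, a ratio of 0.336 (0.307 to 0.368), where 1000 random draws by chromosome length gave 0.909 to 1.12. Per protein-coding gene the ratio was 0.501. With the higher-scoring peaks alone the ratio of densities per Mb was 0.155. The X chromosome also had the highest boundary share, 72.9% of its peaks against 41.8 to 59.2% on autosomes. The Y chromosome had 2 peaks, and whether reads could be placed uniquely on it was not examined.

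**Figure D4:**
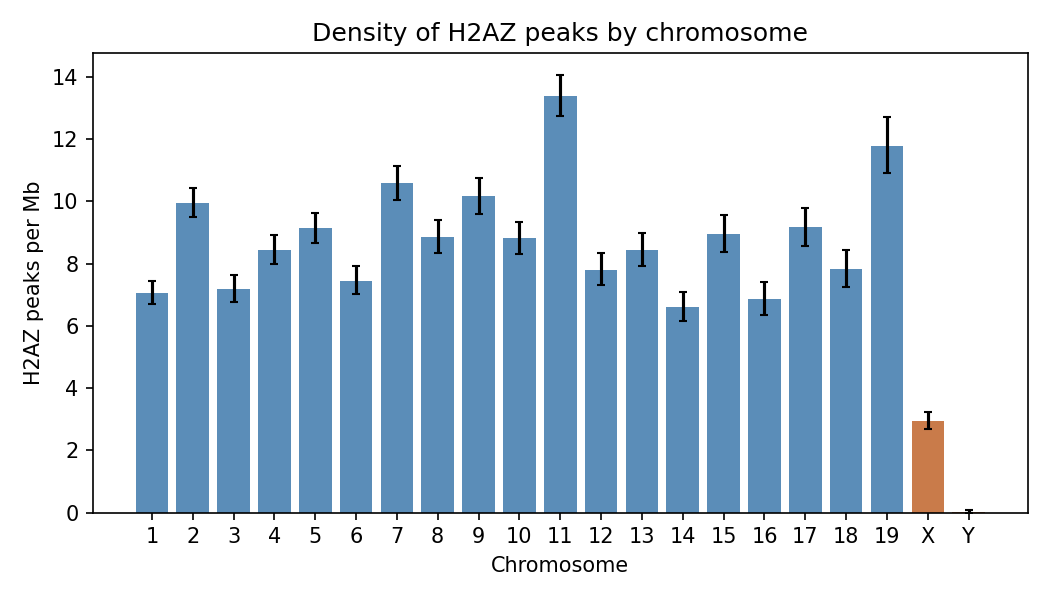
H2AZ peaks per Mb on each chromosome, with autosomes in blue, X and Y in orange and 95% Poisson intervals as error bars. The X chromosome, at 2.95 peaks per Mb, lay below every autosome, the lowest of which had 6.61.

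The last question concerned peaks away from gene boundaries. A midpoint over 5 kb from any boundary was found for 8949 peaks (41.5%), of which 3217 lay inside protein-coding genes and 5732 between them. They were narrower and lower than boundary peaks, with a median width of 1617 against 2180 bp and a median score of 8.05 against 16.7. The genes with the most such peaks, named after their values were seen, were Maml3, a coactivator gene of Notch signalling, and Shroom3, each with 10, followed by Pakap and Rad51b with 9 each. This order is by count, without regard to gene length. Per 100 kb, Maml3 had 2.39, Shroom3 3.54, Pakap 1.95 and Rad51b 1.63, below the 5.49 of Wdr95, which had 7 peaks. The 5 widest peaks of the list lay on chromosome 7 from 38173338 to 38180829 (7492 bp, score 6.59, 6134 bp from the boundary of 1600014C10Rik), at the protocadherin genes Pcdh10 (7247 bp, chromosome 3, 45374921 to 45382167) and Pcdh7 (7070 bp, chromosome 5, 57713801 to 57720870), near Dusp4 (6394 bp, chromosome 8, 34804045 to 34810438) and in the interior of Zmynd8 (5990 bp, chromosome 2, 165883775 to 165889764).

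Windows of 100 kb with many peaks were then listed. The window on chromosome 11 from 69000001 to 69100000 held 14 peaks with a highest score of 24.1, and contains Pfas, Ctc1, Aurkb, Borcs6, Tmem107, Vamp2 and Per1 with 11 tRNA genes, although only 2 of the peaks lay within 1 kb of a tRNA gene. The window on chromosome 2 from 30600001 to 30700000 also held 14 peaks, around Cstad and 4 long non-coding RNA genes. The window on chromosome 13 from 23400001 to 23500000 held 12 peaks, 11 of them within 1 kb of a tRNA gene, and contains Abt1, Btn1a1 and Btn2a2 with 22 tRNA genes. The window that follows the one on chromosome 2 also held 12 peaks.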

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

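Both results here are signals in data that the comparisons did not use. The 46 peaks out of order on their chromosomes had a median score of 9.46, and 38 of them lay before the first annotated gene of the chromosome they are listed on, where 0 of the other peaks lay. The peak numbers absent from the list came to 11054.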

How the results depend on the processing

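The boundary excess (47.0 to 79.0% of peaks), the 3 location classes and the low X density kept their direction and their side of the threshold under the alternatives run for them, and the numbers of genes with a boundary peak (9659 to 13248) and of distal peaks (7498 to 10395) stayed within 1.5 times. Keeping the higher-scoring peaks left, by construction, 10876 peaks, 24.5 Mb, a median width of 2208 bp and a median score of 17.9. Of 126 gene list values under alternatives, 95 kept direction and call; 12 lost a call, 8 gained one and 11 changed direction, and the cause was not tested unless named. With the higher-scoring peaks, the shares of radial glia (16.7%), intermediate progenitors (35.7%), neurons (38.9%) and chromatin modifiers (52.9%) crossed that of other genes, cell cycle (59.3%) and housekeeping (50.0%) lost their calls, developmental regulators (10.0%) and radial glia gained lower calls, 2 lists were called higher in place of 4 and 7 lower in place of 5. The housekeeping call was lost with windows of 500 bp (81.25%) and 5 kb (87.5%). Intermediate progenitors gained a call at 2 kb (92.9%) and 5 kb (92.9%) and radial glia at 2 kb (83.3%). At 5 kb the histone call was lost (50.8%) and the uncalled astrocyte and oligodendrocyte (71.4%) and chromatin modifier (64.7%) shares rose above other genes. The following were chosen after seeing the data. Matched random lists had a mean share of 41.8% for radial glia and 36.2% for intermediate progenitors, which gained calls, 61.7% for housekeeping and 37.1% for histones, which lost theirs, and 48.6% for erythroid genes, below the uncalled list. Among genes with no other boundary within 2 kb, where fewer genes were tested, intermediate progenitors gained a call (90.9%), microglia (11.1%), Hox (26.9%), terminal genes (18.75%), housekeeping (88.9%) and H2AZ turnover (100%) lost theirs, chromatin modifiers (50.0%) and histones (50.0%) crossed other genes, and 1 list was called lower in place of 5. Counting any peak in the gene, intermediate progenitors gained a call (92.9%), and astrocytes and oligodendrocytes (64.3%) and chromatin modifiers (70.6%) crossed other genes without a call. Alternatives that need strand or sequence were not run. No paired analysis was possible because each group had 1 library, and without read numbers a missing peak cannot be told from shallow sequencing.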

Other observations

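The gene families and biotypes in the first 2 paragraphs, and the share of peak numbers listed on X, were tested only after the results were seen. Of 33 families grouped by gene symbol, 9 had boundary peaks more often than other genes, 8 less often and 16 were not called (Fisher's exact test, two-sided, adjusted over the families). The alternatives under which some list calls ended, such as that of housekeeping genes, were not run for the families. Genes of basic cell machinery led: 70 of 75 mitochondrial ribosomal protein genes (93.3%, Fisher adjusted p = 6.88e-12), 35 of 37 NADH dehydrogenase genes (94.6%), 62 of 72 cytosolic ribosomal protein genes (86.1%), 18 of 20 splicing factor genes of the Srsf and Sf3 series, 32 of 37 DEAD-box helicase genes, 35 of 41 translation initiation factor genes and 32 of 39 proteasome genes. Of the families of neural wiring and signalling, 16 of 18 ionotropic glutamate receptor genes (88.9%, Fisher adjusted p = 0.00801), with Gria2 at 12.5 and Grin2b at 12.2, and 18 of 22 ephrin and Eph receptor genes (81.8%, Fisher adjusted p = 0.0317) had a boundary peak, but GABA-A receptor genes (11 of 19, Fisher adjusted p = 1), semaphorin genes (14 of 20, 0.374) and potassium channel genes of the Kcn series (51 of 80, 0.237) were not called.

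The families with few boundary peaks were 350 vomeronasal receptor genes (2 with a peak), 42 beta-defensin genes (1), 55 clustered protocadherin genes (5, Fisher adjusted p = 7.28e-12), 93 cytochrome P450 genes (24), 49 keratin genes (13), 33 interleukin genes (9) and 31 chemokine genes (6). Of 9 Pax genes 1, Pax6, had a boundary peak (Fisher adjusted p = 0.0277), with a score of 7.16. Outside protein-coding genes and over 5 kb from their boundaries, 890 of 6436 long non-coding RNA genes had a boundary peak (13.8%), against 8.88% at positions 10 kb away, and 108 of 6731 pseudogenes (1.60%), against 3.32%. Whether reads could be placed uniquely at pseudogenes and in families of similar genes was not examined. A missing peak there need not mean missing H2AZ.

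The X chromosome had 0.336 times the autosomal peak density. Removal from the list does not account for it, since 76.9% of the peak numbers on X were listed (interval 73.5 to 80.2%) against 66.0% on autosomes. Gene content cannot be told apart as a partial cause, since without predicted and receptor genes the share of genes with a boundary peak was still 0.750 times that of autosomes (interval by a normal approximation, 0.697 to 0.807), and the interval reached above the bound set in advance for ruling it out. This interval treats genes as independent. Fewer copies of X is a candidate explanation, as the median score of boundary peaks on X was 0.579 times that on autosomes (bootstrap interval 0.562 to 0.618), while peaks away from boundaries had similar medians of 8.20 and 8.35 and 0.187 times the autosomal density (interval 0.156 to 0.221), and medians of listed peaks cannot show peaks too low to be listed. The sex of the embryos is not in the labels, and no biological explanation was tested.

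Of 281 tRNA genes away from protein-coding genes, 43.8% had a peak within 1 kb, against 19.4% at positions 10 kb away. Of 133 tRNA genes over 5 kb from any other annotated gene, 40.6% still had a peak (interval 32.2 to 49.5%), against 18.4% (13.9 to 23.6%) at positions 10 kb away. These intervals did not overlap, the result set in advance as going against boundaries of other annotated genes as the cause. However, they treat tRNA genes as independent, while the 123 of 281 genes with a peak shared 75 peaks. The intervals are therefore too narrow, and this explanation is not settled. Reads of near-identical copies piling up on the genes cannot be told apart, because 26.7% of 75 peaks had a midpoint within 200 bp of a tRNA gene (interval 17.1 to 38.1%), between the bounds of 25 and 50% set in advance. The median distance was 384 bp. H2AZ beside tRNA genes remains possible, and no biological explanation was tested.

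Hox genes had few boundary peaks (7 of 39), with 3 of 11 in the Hoxa cluster, 0 of 10 in Hoxb, 0 of 9 in Hoxc and 4 of 9 in Hoxd. Peaks left out of the list do not account for all of the 32 genes without a peak, since at most 8 peak numbers are missing over the 4 clusters, where 8 peaks were listed. Whether they account for a part is left open. The rate of missing numbers was 0.751 per 100 kb against 0.414 over the genome, but it rests on at most 8 numbers, so no excess can be read from it. Peaks beyond the 1 kb windows did not close the gap, since within 5 kb 25.6% of Hox genes (interval 13.04 to 42.1%) had a peak, against 60.9% of other genes. The interval stayed below other genes, the result set in advance as going against this explanation. However, it treats Hox genes as independent, while they lie in 4 clusters, so it may be too narrow. The call was kept against random lists matched on gene length and neighbouring boundaries (mean share 51.2%, permutation adjusted p = 0.0009). These lists were not matched on lying in a cluster. It was lost among genes with no other boundary within 2 kb, where fewer genes were tested and the share was 26.9% against 47.6% of other genes. Among other genes, close boundaries went with more peaks, as the share over all of them was 55.5%. The Hox genes went the other way, since 0 of the 7 with a peak had another boundary within 2 kb. The packing of the clusters is therefore left open. No biological explanation was tested.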
